A study of Mus musculus with 5 samples.

How the data were processed

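Total RNA from flash-frozen tissue labelled dorsolateral prostate of 2 tamoxifen control and 3 Ghr deletion mice was extracted with a NucleoSpin kit and made into libraries with Illumina's TruSeq Stranded Total RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.422, STAR 2.5.3a, RSEM 1.3.0 and the mouse genome build GRCm38. The annotation release, the strand setting and other parameters are not given in the sources used here, so counts of overlapping or antisense genes may share reads. Per the file headers, the authors deposited 1 table per library with RSEM's expected counts, which need not be whole and are not normalized, and its TPM, which are relative to gene length and to all genes of the library. The tables list the same 51912 gene IDs. Of these, 279 had no symbol in the gene name table used (99.5% matched), and 51719 were present in GENCODE release M21 for GRCm38, from which positions were taken.

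Expected counts were rounded to whole numbers. Groups and replicate numbers came from the sample titles. The comparison was fitted over all 5 libraries with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr on the groups, which left 18615 genes, TMM normalization, glmQLFit with the robust option and glmQLFTest with the group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. CPM are counts scaled to the TMM-adjusted library size in the usual unit of that name, also for genes outside the filter. The TMM factors were 0.491 and 1.50 for the controls and 1.00, 0.843 and 1.61 for the deletion libraries. The 50 genes of highest mean count held 74.7% and 28.2% of counts in the controls and 50.9%, 50.4% and 22.7% in the deletion libraries. A count of 3, used as the floor for undetected genes, stood for 0.128 and 0.145 CPM in the controls and 0.105, 0.0940 and 0.0557 CPM in the deletion libraries. Shares of counts carry 95% Wilson intervals, here at most ± 0.0237 percentage points. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

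With 2 controls, the spread between animals sets the precision. The median SE of a log2 fold change was 0.529 and the common biological coefficient of variation 0.520. Correlations of log2 CPM across genes were 0.897 between the controls, 0.938, 0.932 and 0.908 among the deletion libraries, and up to 0.955 across groups (control replicate 2 with deletion replicate 3). The fit was tested on 5 simulated sets of 18615 genes drawn from the fitted means, dispersions and library sizes: it called 0.613% of genes changed 2-fold, 42.2% of those changed 8-fold, 82.5% of those changed 32-fold and 0.0489% of unchanged genes. With the mitosis list simulated at -3, camera called it in 5 of 5 sets with the preset correlation and in 4 of 5 with an estimated one, and called 3 and 0 of 140 tests of other lists. Simulated genes were drawn independently of each other, so these list rates do not carry over to lists of correlated genes. In the data the estimated correlation of the mitosis list was 0.861.

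Gene lists, the rule for named genes, the design and the alternatives were fixed before the data were examined. There were 31 lists, matched by exact symbol: growth hormone (GH) axis, mitosis, DNA replication, androgen response, prostate secretory, seminal vesicle, luminal and basal epithelium, neuroendocrine, urothelium, fibroblast and collagen, smooth muscle, skeletal muscle, adipocyte, T cell, B and plasma cell, macrophage, neutrophil, endothelium, nerve and Schwann cell, p53 targets, interferon response, unfolded protein response, oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, EMT regulators, MAPK feedback, immediate early, circadian clock and mitochondrial genome. The urothelium and B and plasma cell lists had fewer than 4 tested members, which left 29 tested with camera at an inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also bases its p-values on the residual degrees of freedom, here 3. The camera runs therefore differ in more than the correlation. Members were also adjusted over each list alone.

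By that rule, named genes were Ghr, the 10 genes of smallest p in each direction among those that passed with a mean of at least 1 CPM, non-overlapping groups and a symbol that is neither a predicted gene nor a pseudogene (or, with fewer than 5, the 5 of smallest unadjusted p, given as not passed), 4 further GH axis members, 2 mitosis and 2 androgen response members, 2 to 4 members of each other list past the threshold, and the 3 genes of highest mean CPM. Further list members were given as examples. The organ markers Akr1b7, Upk3a and Pbsn and the genes of the closing section were chosen after their values were seen. Ghr was also tested with an exact permutation test. Some marker genes, and the tests that used them, are not reported here.

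The alternatives were DESeq2's size factors in edgeR, upper-quartile factors, library sizes without the 50 most abundant genes, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, edgeR without the robust option, glmTreat at a fold change of 1.5, each library left out in turn, the replicate number as a block, and both other list tests. Leaving out a control leaves 1, which is then assumed to vary like the deletion libraries. A fit without both control replicate 1 and deletion replicate 3 was added after seeing the data, as was an estimated correlation without control replicate 1.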

Results

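RNA was sequenced from tissue that the labels give as dorsolateral prostate, the dorsal and lateral lobes of the mouse prostate, of 5 male mice aged 7 months. Prostate marker genes were nearly absent from 4 of the 5 libraries, with Pbsn at 1, 4, 8 and 3 counts. All carried the SV40 large T antigen under the C3(1) promoter, a transgene that drives prostate tumour formation, together with floxed alleles of Ghr, the growth hormone receptor gene. All received 250 mg/kg tamoxifen daily for 5 days, and tissue was taken 1 month after the last dose. The 3 libraries labelled Ghr deletion came from mice that also carried a tamoxifen-inducible Cre recombinase at the ROSA26 locus, and the 2 tamoxifen control libraries came from mice whose labels list no Cre, so every difference between the groups is also one between mice with and without Cre. The series describes the libraries of each group as biological replicates. Total counts were 47656212 and 13812454 in control replicates 1 and 2, and 28536636, 37910327 and 33414067 in deletion replicates 1, 2 and 3.

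The comparison asks how the tissue's transcripts differed between mice labelled Ghr deletion and tamoxifen controls, 1 month after the last dose. Loss of the receptor itself was not measured. Mitosis genes fell in the deletion libraries as a list (median log2 fold change -2.97 over 22 genes; camera, adjusted p = 6.64e-39; adjusted p = 0.338 with an estimated correlation). Top2a, a topoisomerase of dividing cells, had 30.0 ± 26.2 CPM (library-scaled counts; SD, n = 2) in the controls and 1.37 ± 0.316 (SD, n = 3) in the deletion libraries. Lists of interferon response, T cell, endothelial, fibroblast and macrophage genes and the growth hormone (GH) axis list were lower by the same test, and 5 lists were higher. With an estimated correlation 0 of the 29 lists passed (adjusted p of 0.338 to 0.578 for those that had). Over all genes 0 passed in edgeR, 915 had an unadjusted p under 0.05 there (chance gives 931), DESeq2 passed 164 and limma-voom 0, and Ghr passed in none. Seminal vesicle and prostate secretory genes differed widely between libraries of the same group. Unlike tissue content bears on every list, the GH axis list included, and cannot be told apart here from an effect of Ghr deletion.

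Ghr itself had 22.8 ± 11.9 CPM (SD, n = 2) in the controls and 13.7 ± 6.55 (SD, n = 3) in the deletion libraries. The controls read 14.4 and 31.3 CPM and the deletion libraries 8.13, 20.9 and 12.1 CPM, so control replicate 1 lay inside the deletion range. The log2 fold change was -0.73 (SE 0.515, 95% interval -1.97 to 0.50; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.995). A two-sided exact permutation test of the log2 CPM gave p = 0.4, where 0.1 is the smallest value that 2 against 3 libraries allow. The fold change was -0.071 without control replicate 2, -1.19 without control replicate 1, -0.45 without deletion replicate 1 and -1.17 without deletion replicate 2. The authors' TPM for Ghr were 0.81 and 12.12 in the controls and 1.23, 6.34 and 8.76 in the deletion libraries. Ghr (ENSMUSG00000055737) lies on the minus strand of chromosome 15 from 3317760 to 3583492 (GRCm38), and its count covers all 10 annotated transcripts. The labels name no deleted exon, so the gene-level count does not isolate the deleted part and is a weak check of the labels.

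The GH axis list, which holds the receptor, its JAK-STAT relays and the insulin-like growth factor (IGF) system, fell, with a median log2 fold change of -0.64 over 21 tested genes (camera, adjusted p = 0.0142; adjusted p = 0.338 with an estimated correlation). In it 12 genes were lower and 9 higher. The estimated correlation between members was -0.0303, below the preset 0.01, so the lost call cannot be put down to members moving together. Igfbp5, an IGF-binding protein, had 82.6 ± 24.6 CPM (n = 2) in the controls and 20.0 ± 8.47 (n = 3) in the deletion libraries, a log2 fold change of -2.05 (SE 0.451). Igfbp4 had 18.4 ± 6.04 against 7.41 ± 0.558 CPM. Stat5b, a transcription factor activated by the receptor, read 200 and 49.5 CPM in the controls and 46.4, 24.9 and 37.3 in the deletion libraries. Cish, a STAT5-induced inhibitor of cytokine signalling, had 23.4 ± 4.29 against 10.1 ± 4.19 CPM. These 4 genes had all deletion libraries below both controls, and none passed the edgeR test over all genes (adjusted p of 0.985 to 0.991), while DESeq2 passed Igfbp5 (adjusted p = 0.0197). Igfbp3 and Igfbp6 were also lower in all deletion libraries, at 40.9 ± 20.7 against 14.2 ± 8.46 and 4.13 ± 2.08 against 1.46 ± 0.707 CPM. The insulin receptor gene Insr, at 145 ± 8.16 against 235 ± 61.3 CPM, its adaptor Irs2, at 12.2 ± 6.81 against 27.3 ± 10.9, and the growth factor Igf2, at 3.56 ± 0.986 against 8.11 ± 3.37, were higher in all deletion libraries. Groups overlapped for Socs2, Igf1r and Igf1: Socs2 had 26.6 ± 22.0 against 31.3 ± 20.7 CPM, Igf1r 267 ± 187 against 341 ± 93.8, and Igf1 10.8 ± 7.69 against 6.95 ± 6.25. No member passed in edgeR adjusted over the list alone. Groups did not overlap for 6 lower and 3 higher members, where chance gives 20% of genes in all. The list's median was -0.23 without control replicate 1 and -0.23 without control replicate 2, and without deletion replicate 1 it was -0.45 and no longer passed (adjusted p = 0.0942). With no filter on low counts it was -0.27.

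**Figure D1:**
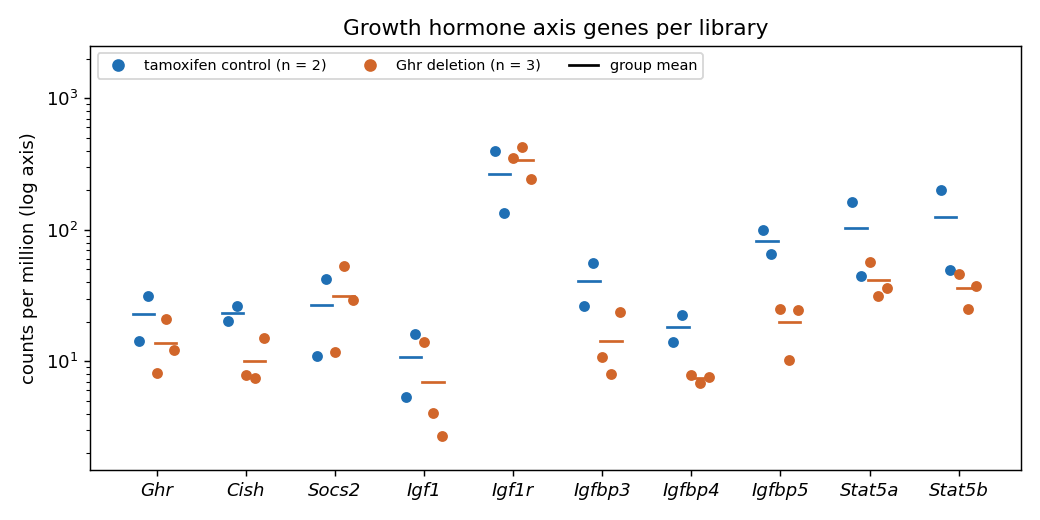
CPM (log axis) of 10 growth hormone axis genes in each library, with tamoxifen controls (n = 2) in blue, Ghr deletion libraries (n = 3) in orange and a bar at each group mean. Igfbp4, Igfbp5, Cish and Stat5b have all deletion points below both control points, while for Ghr control replicate 1, at 14.4 CPM, lies among the deletion points.

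By camera with its preset correlation, mitosis genes gave the smallest p of all lists. All 22 members were below both controls in all 3 deletion libraries, where chance gives 10% of genes on that side and 20% in all, and the list fell, with a median log2 fold change of -2.97 (SD over members 0.785; camera, adjusted p = 6.64e-39; adjusted p = 0.338 with an estimated correlation). The estimated correlation between members was 0.861, so the 22 genes moved together and do not count as 22 separate observations. All 22 passed adjusted over the list alone and 0 over all genes by edgeR, where 22 had an unadjusted p under 0.05. DESeq2 passed 13 of them over all genes, all lower. Top2a, the topoisomerase that untangles replicated chromosomes, read 48.5 and 11.5 CPM in the controls and 1.47, 1.63 and 1.02 in the deletion libraries (log2 fold change -4.45, SE 0.653, adjusted p = 0.985). Cenpf, a kinetochore protein, read 45.8 and 7.12 against 1.16, 1.22 and 0.575 CPM. Mki67, the Ki-67 proliferation antigen, read 119 and 20.3 against 2.45, 6.33 and 2.02 CPM, and Cdk1, the mitotic kinase, 6.12 and 2.52 against 0.806, 0.783 and 0.965. The DNA replication list also fell, with a median log2 fold change of -0.66 over 22 genes, 21 of them lower (adjusted p = 2.05e-07; adjusted p = 0.347 with an estimated correlation). Of these 3 passed in edgeR adjusted over the list alone and 0 over all genes, where DESeq2 passed the same 3: Uhrf1, a hemimethylated-DNA reader, at 10.8 ± 8.31 against 0.972 ± 0.255 CPM, and the helicase subunits Mcm3, at 8.83 ± 3.12 against 2.60 ± 0.403, and Mcm5, at 7.77 ± 3.46 against 2.05 ± 0.382. Pcna, the replication clamp, was 29.8 ± 1.35 against 28.9 ± 7.27 CPM. Control replicate 1, the library with 34.7% of its counts in seminal vesicle genes, carried much of the size: without it the medians were -1.67 for mitosis (adjusted p = 2.59e-18; adjusted p = 0.234 with an estimated correlation) and -0.27 for replication (adjusted p = 0.00965). Without control replicate 1 and deletion replicate 3, a choice made after seeing the data, they were -1.59 and -0.32, and the replication list did not pass (adjusted p = 0.175).

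**Figure D2:**
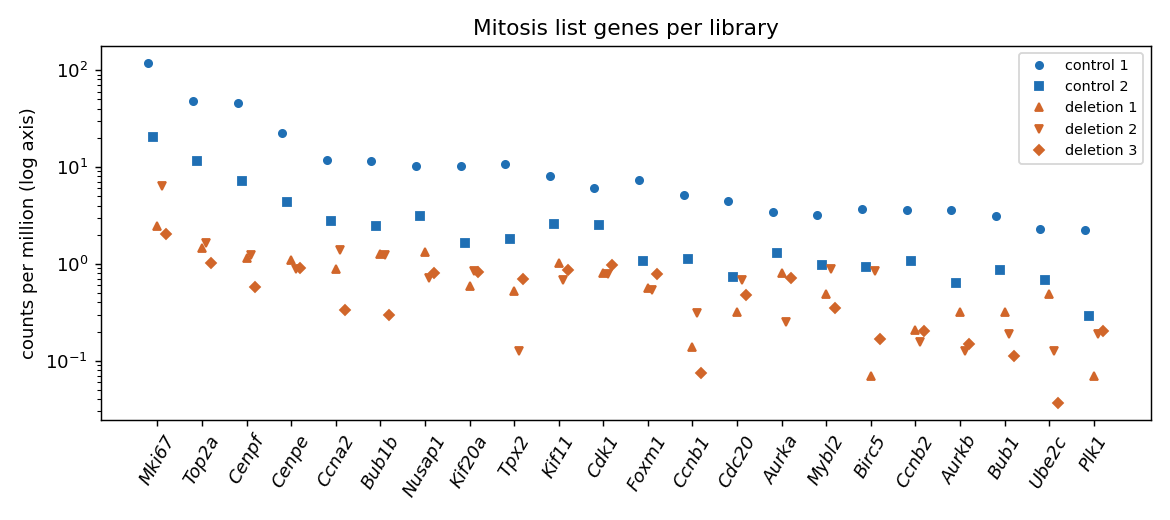
CPM (log axis) of the 22 mitosis list genes in each library, ordered by mean level, with controls in blue and deletion libraries in orange. Control replicate 1 is highest and control replicate 2 lies between it and the deletion libraries, as for Top2a at 48.5, 11.5 and at most 1.63 CPM.

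The interferon response list fell, with a median log2 fold change of -1.71 and 16 of 16 members lower by fold change (camera, adjusted p = 3.65e-14; adjusted p = 0.338 with an estimated correlation), and its median was -1.03 without control replicate 1. Groups did not overlap for 10 of the 16, all lower, where chance gives 20% of genes in all. Deletion replicate 3 was the highest library for Ifit3, at 206 CPM against 14.6 and 146 in the controls, and for Ifit2, at 15.8 against 9.28 and 14.0. Of the list's members 7 passed in edgeR adjusted over the list alone and 0 over all genes, where 8 had an unadjusted p under 0.05 and DESeq2 passed 4 (Isg15, Oas2, Irf7 and Ifi44). Examples were Isg15, a ubiquitin-like antiviral protein, at 3.74 ± 2.34 against 0.599 ± 0.0679 CPM, and the transcription factor Irf7 at 13.9 ± 6.27 against 3.30 ± 1.11. The T cell list fell, at a median of -1.80 with 11 of 12 members lower (adjusted p = 4.56e-09), from low levels: Cd8a, a co-receptor of cytotoxic T cells, had 3.04 ± 2.06 against 0.487 ± 0.236 CPM and Cd8b1 1.20 ± 0.908 against 0.140 ± 0.153. The endothelium list fell, at -0.93 with 11 of 11 lower (adjusted p = 2.63e-07), including Eng at 10.3 ± 3.47 against 3.36 ± 0.983 CPM and Tie1 at 5.79 ± 0.923 against 1.99 ± 0.496. With an estimated correlation the adjusted p = 0.338 for both. The fibroblast and collagen list fell, at -0.99 over 16 genes, 13 of them lower (adjusted p = 9.41e-07; adjusted p = 0.398 with an estimated correlation), with Sparc at 66.5 ± 3.78 against 31.1 ± 11.8 CPM and Thy1 at 11.6 ± 3.04 against 3.62 ± 1.99. The macrophage list fell, at -0.81 with 12 of 12 lower (adjusted p = 7.90e-05; adjusted p = 0.338 with an estimated correlation), with lysozyme gene Lyz2 at 30.6 ± 16.3 against 14.3 ± 2.11 CPM and complement gene C1qa at 11.9 ± 2.71 against 6.15 ± 0.747. No T cell, endothelium, fibroblast or macrophage member passed in edgeR adjusted over its list alone, or over all genes in edgeR or DESeq2. Without control replicate 2 the fibroblast list stood at -0.59 (adjusted p = 0.0514) and the macrophage list at -0.53 (adjusted p = 0.139).

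Secretory transcripts differed widely between libraries of the same group. The seminal vesicle list, the genes of the main seminal fluid proteins, took 34.7% of all counts in control replicate 1, 0.847% in control replicate 2, and 24.2%, 26.3% and 0.352% in deletion replicates 1, 2 and 3 (95% Wilson intervals of at most ± 0.0157 percentage points). Svs6 had 41009 and 116 CPM in the controls and 10.8, 6.48 and 5.92 in the deletion libraries, and Spinkl 6324 and 18.3 against 0.841, 0.157 and 1.15. By contrast Svs2, the gene of highest mean level, read 193471 and 2213 CPM in the controls and 191558, 270169 and 1753 in the deletion libraries. The list's median log2 fold change was -11.37 over 9 genes, 8 of them lower (camera, adjusted p = 7.47e-10; adjusted p = 0.338 with an estimated correlation), and -3.90 without control replicate 1. The prostate secretory list was tested without its genes short of the low-count filter, the prostate marker Pbsn among them. It had a median of -4.10 over 10 genes, 7 of them lower (adjusted p = 6.68e-06; adjusted p = 0.338 with an estimated correlation). It was led by Spink1, at 4390 and 11.2 CPM against 0.421, 0.0313 and 0.408, and Ceacam10, at 22402 and 44.5 against 12.8, 4.17 and 4.38, both of which the seminal vesicle also makes. Its median was -0.24 without control replicate 1, -2.73 without deletion replicate 1, and 0.043 (adjusted p = 0.165) without control replicate 1 and deletion replicate 3. In each list 6 members passed in edgeR adjusted over the list alone and 0 over all genes, where 6 of each had an unadjusted p under 0.05. DESeq2 passed 6 seminal vesicle members over all genes, Svs6 and Spinkl among them, and 3 prostate secretory members (Spink1, Ceacam10 and Sbp), all lower. The 7SL RNA genes Rn7s1 and Rn7s2, near-identical copies whose reads cannot be told apart with certainty, took 21.8% and 7.25% of counts in the controls and 10.5%, 5.78% and 2.03% in the deletion libraries (at most ± 0.0137 points).

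The prostate markers Pbsn and Hoxb13 were scarce. Pbsn, the prostate-specific probasin gene, had 411 counts in control replicate 1 and 1, 4, 8 and 3 counts in control replicate 2 and deletion replicates 1, 2 and 3. Hoxb13, a prostate lineage factor, had 13, 0, 0, 1 and 4 counts in the same order, and 3 counts stand for 0.145 CPM in control replicate 2 and 0.105 CPM in deletion replicate 1. The androgen response list had a median log2 fold change of 0.053 (camera, adjusted p = 0.717). Its members of smallest p were Abcc4, an organic anion exporter, at 12.8 ± 5.50 against 34.7 ± 3.65 CPM and Steap4, a metalloreductase, at 22.0 ± 7.51 against 5.40 ± 3.28. DESeq2 passed 1 member over all genes, Acpp, a prostatic acid phosphatase, at 3.68 and 20.4 CPM against 109, 245 and 26.7 (adjusted p = 0.0420), and passed neither of those. Akr1b7, an aldo-keto reductase abundant in the vas deferens, read 4.92 and 890 CPM in the controls and 3484, 3250 and 9.26 in the deletion libraries. Upk3a, a uroplakin of the bladder lining, had 1046 counts in deletion replicate 3 and 0 in the other libraries. The basal epithelium list fell, with a median of -0.83 over 10 genes, 9 of them lower (adjusted p = 0.000505; adjusted p = 0.347 with an estimated correlation), with Krt15 at 9.87 ± 1.38 against 2.18 ± 1.02 CPM, its 1 member past the threshold in edgeR adjusted over the list alone and in DESeq2 over all genes, and Krt14 at 12.2 ± 2.57 against 2.70 ± 1.58. That median was -0.15 without control replicate 1 and -0.54 without deletion replicate 2. The luminal epithelium list had a median of 0.27 (adjusted p = 0.781).

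**Figure D3:**
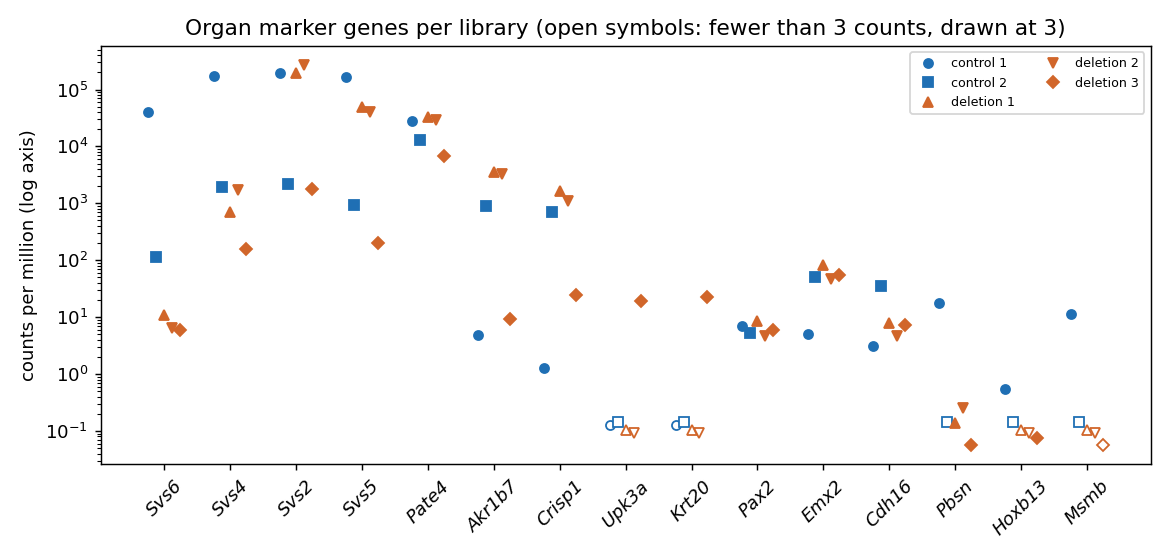
CPM (log axis) of 15 organ marker genes in each library, with controls in blue and deletion libraries in orange and open symbols for fewer than 3 counts, drawn at the level of 3 counts. Svs6 and Svs4 are highest in control replicate 1, Svs2 and Svs5 in control replicate 1 and deletion replicates 1 and 2, and Upk3a and Krt20 in deletion replicate 3.

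Gene by gene, 0 of 18615 genes passed in the edgeR quasi-likelihood test (smallest adjusted p = 0.985). At an unadjusted p under 0.05 there were 915 genes, 314 higher and 601 lower, where chance alone gives 931. DESeq2 passed 164 genes, 36 higher and 128 lower, and limma-voom 0. Without control replicate 2 the edgeR count was 48 and without deletion replicate 3 it was 2. Without control replicate 1 and deletion replicate 3 it was 85. In 3656 genes, 19.6% of those tested, all deletion libraries lay on one side of both controls, where chance gives 20%. Among genes with such separation, a mean of at least 1 CPM and a symbol that is not a predicted gene, those of smallest p on the higher side were Exph5, a Rab27 effector, at 18.2 ± 4.94 against 64.1 ± 13.4 CPM (log2 fold change 1.82, SE 0.346), and the transcriptional repressor Bcl11a at 5.31 ± 0.367 against 17.5 ± 1.77. They were followed by the interleukin-13 decoy receptor Il13ra2 at 0.355 ± 0.320 against 5.38 ± 2.53, the T cell co-stimulator Icosl at 12.1 ± 1.67 against 30.5 ± 3.45, and Snap91, a clathrin assembly protein, at 0.128 and 0 CPM against 8.03, 15.8 and 1.35. On the lower side they were Top2a and Cenpf, the ferroxidase Heph at 137 ± 94.7 against 16.9 ± 3.99 CPM (log2 fold change -3.02, SE 0.489), the lymphoid chemokine Ccl21a at 6.18 ± 2.99 against 0.662 ± 0.196, and Rnu3a, a U3 small nucleolar RNA. Near-identical copies of Ccl21a can share its reads. Rnu3a had 132 and 47 counts in the controls and none in the deletion libraries under 1 of 2 IDs at the same place, whose reads cannot be assigned to either. Both IDs summed had 5.21 ± 4.01 against 1.99 ± 1.29 CPM, with control replicate 2, at 2.37 CPM, inside the deletion range. None of these 10 genes passed over all genes in edgeR (adjusted p = 0.985 for each), and all 10 were among the DESeq2 calls (adjusted p from 5.59e-07 for Rnu3a to 0.0232 for Icosl).

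Of the 29 lists tested, 16 passed camera with its preset correlation, 5 higher and 11 lower, and 0 passed with an estimated correlation or with fry, which tests a list without comparing it with other genes. At an unadjusted p under 0.05 there were 2 lists with an estimated correlation and 5 with fry. For each of the 5 higher lists, leaving out a single library ended the call. The skeletal muscle list rose, with a median log2 fold change of 1.69 (adjusted p = 0.00227; adjusted p = 0.434 with an estimated correlation), with Tnnt3 at 0.140 ± 0.0764 against 0.997 ± 0.742 CPM and Atp2a1 at 0.0242 ± 0.0342 against 0.403 ± 0.270. Its median was 0.29 without deletion replicate 1 (adjusted p = 0.777), 2.56 without control replicate 2 and 1.16 among genes with a mean of 1 CPM or more (adjusted p = 0.158). The neuroendocrine list rose by a median of 1.53 (adjusted p = 0.00605; adjusted p = 0.434 with an estimated correlation), with Syp at 0.121 ± 0.171 against 0.776 ± 0.173 CPM and Snap25 at 0.0456 ± 0.00398 against 0.581 ± 0.506. Its median was -0.11 without deletion replicate 3 (adjusted p = 0.244), 3.66 without control replicate 2 and 1.14 without control replicate 1 (adjusted p = 0.412), and among genes with a mean of 1 CPM or more it was -0.038 (adjusted p = 0.296). The adipocyte list rose by a median of 0.98 (adjusted p = 0.000615; adjusted p = 0.370 with an estimated correlation), with Fabp4 at 0.685 and 4.02 CPM against 1.40, 32.7 and 28.8 and Pck1 at 0.169 ± 0.240 against 1.35 ± 0.911. The adipocyte median was 0.39 without control replicate 1 (adjusted p = 0.173), 4.92 without control replicate 2 and 0.59 without deletion replicate 2. The circadian clock list rose by a median of 0.54 (adjusted p = 0.0123; adjusted p = 0.578 with an estimated correlation), with Npas2 at 0.830 ± 0.763 against 3.42 ± 1.44 CPM and Arntl at 7.99 ± 5.41 against 22.0 ± 17.8. Its median was -0.071 without deletion replicate 2 (adjusted p = 0.933) and 0.68 without control replicate 2 (adjusted p = 0.109). The MAPK feedback list rose by a median of 0.41 (adjusted p = 0.0117; adjusted p = 0.564 with an estimated correlation), with Dusp4 at 16.6 and 7.70 CPM against 82.7, 54.9 and 9.43 and Spry1 at 8.04 and 12.0 against 13.9, 52.7 and 16.1. It did not pass without control replicate 1 (0.23, adjusted p = 0.314), deletion replicate 1 (0.50, adjusted p = 0.0942) or deletion replicate 2 (0.32, adjusted p = 0.224), and its median was 0.94 without control replicate 2. Without control replicate 1 and deletion replicate 3, the skeletal muscle list (1.63, adjusted p = 0.108), the adipocyte list (0.43, adjusted p = 0.275) and the neuroendocrine list (0.89, adjusted p = 0.984) did not pass. With all libraries and the group as the only term, no member of these 5 lists passed in edgeR adjusted over its list alone, or over all genes in edgeR or DESeq2.

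The other lists did not pass. Their median log2 fold changes were -0.54 for EMT regulators (adjusted p = 0.0652), -0.38 for the mitochondrial genome (0.0860), 0.23 for oxidative phosphorylation (0.108), -0.20 for cholesterol synthesis (0.117) and 0.40 for nerve and Schwann cell (0.125). They were -0.25 for the unfolded protein response (0.177), -0.23 for neutrophil (0.201), 0.33 for smooth muscle (0.280), 0.080 for p53 targets (0.332), -0.091 for immediate early (0.464) and 0.14 for fatty acid synthesis (0.955), whose mean of -0.10 and test lie the other way. Without control replicate 1, 4 of the 13 lists that had not passed did so: EMT regulators at -0.75 (adjusted p = 0.00127), immediate early at -0.13 (0.00410), the mitochondrial genome at 0.44 (0.00994) and cholesterol synthesis at -0.34 (0.0348). With an estimated correlation in that fit, an alternative added after seeing the data, none of these 4 passed (adjusted p = 0.661 for each).

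**Figure D4:**
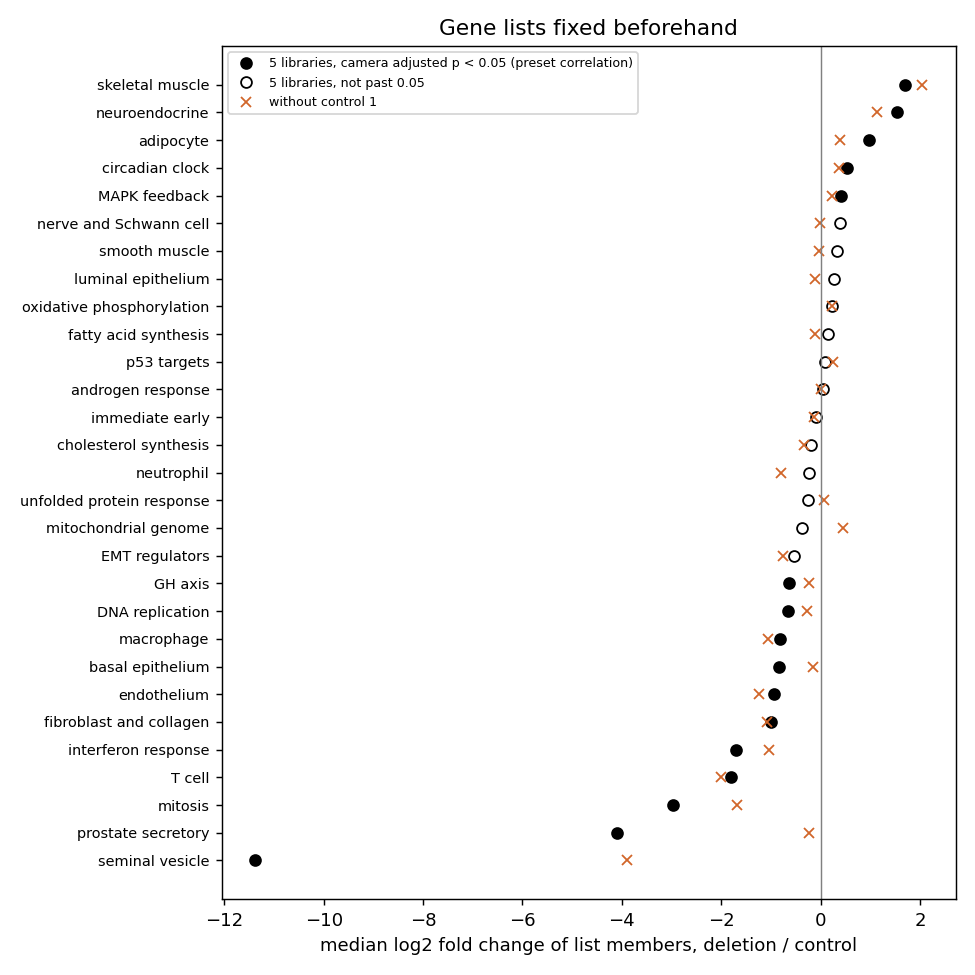
Median log2 fold change (deletion over control) of the members of each of the 29 lists, with filled circles for lists past camera's threshold with the preset correlation, open circles for the others, and crosses for the fit without control replicate 1. The mitosis list lies at -2.97 with all libraries and at -1.67 without control replicate 1, and the seminal vesicle list at -11.37 and -3.90.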

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

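The fits without both control replicate 1 and deletion replicate 3, and with an estimated correlation without control replicate 1, were chosen after seeing the data. The other alternatives were planned. Over the counts, Ghr, the named genes and the 16 lists that passed, 866 values stayed the same, 31 passed newly, 64 no longer passed, 10 reversed and 8 counts moved. A value stayed the same if it kept its direction and its side of the threshold, or, for a count, lay within 1.5-fold. No named gene had passed in edgeR, so a named gene kept its side by not passing again. The 13 lists that did not pass are outside this tally. Genes passed numbered 164 with DESeq2, 8 with the replicate block, 85 without both those libraries, and 0 to 48 with single libraries left out, against 0 in edgeR with all libraries, where 915 had an unadjusted p under 0.05 (chance gives 931); limma-voom gave 0. The Ghr level stayed negative and short of the threshold in 15 alternatives, from -1.19 to -0.071 (adjusted p of 0.920 to 1.00). Lists passed numbered 14 to 18, but 0 with an estimated correlation (also 0 when control replicate 1 was left out) and 0 with fry. The mitosis list stayed negative, from -3.78 to -1.67 with single libraries left out, and did not pass with an estimated correlation (-2.97, adjusted p = 0.338) or fry (-2.97, adjusted p = 0.334), nor with an estimated correlation without control replicate 1 (-1.67, adjusted p = 0.234).

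Among the named genes and the lists that passed, these signs reversed, and the cause was not tested. Without control replicate 1 and deletion replicate 3 the prostate secretory list was 0.043 (lowest -6.06, without control replicate 2), and the Rn7s2 level and Rn7s1 level were 0.81 and 0.86. Without control replicate 1 these 7SL levels were 0.34 and 0.38 (-2.98 and -2.68 without control replicate 2). The Svs2 level was -0.33 without control replicate 2 and -0.018 without deletion replicate 2 (highest 6.70, without control replicate 1 and deletion replicate 3). The neuroendocrine list was -0.038 at a mean of 1 CPM or more and -0.11 without deletion replicate 3 (3.66 without control replicate 2). The circadian clock list was -0.071 without deletion replicate 2 (0.79 without deletion replicate 1). Among the lists that did not pass, the medians of these changed sign without control replicate 1: mitochondrial genome (-0.38 to 0.44), luminal epithelium (0.27 to -0.12), fatty acid synthesis (0.14 to -0.11), unfolded protein response (-0.25 to 0.072), smooth muscle (0.33 to -0.030) and nerve and Schwann cell (0.40 to -0.012).

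The labels give no pairing of replicate numbers. With them as a block, 17 lists passed, the mitosis list was -2.55 (adjusted p = 6.25e-22), Ghr was -0.70 and the neuroendocrine list did not pass (1.52, adjusted p = 0.0639). Deletion replicate 3 was alone in its block in that fit, so it added nothing to the group difference. Depth limits low genes most in control replicate 2, where 3 counts are 0.145 CPM. DESeq2, limma-voom, glmTreat and the fit without the robust option gave no list test.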

Other observations

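All tests below were chosen after the result was seen, except the counts of other splits. DESeq2 passed genes outside the lists that edgeR did not, described here as values chosen after they were seen. Cdkn1c, a cyclin-dependent kinase inhibitor, read 1.88 and 2.95 CPM in the controls and 20.8, 24.8 and 5.12 in the deletion libraries (DESeq2 adjusted p = 0.0197). Gstm1, a glutathione transferase, read 93.3 and 166 against 307, 485 and 608 CPM (DESeq2 adjusted p = 0.0232), and Gpx2, a glutathione peroxidase, 0.342 and 0.920 against 3.61, 2.47 and 3.64 (DESeq2 adjusted p = 0.0331). Pfkfb3, which makes an activator of glycolysis, read 20.0 and 51.8 against 3638, 794 and 62.2 CPM (DESeq2 adjusted p = 0.00199), so deletion replicate 3 lay near the controls. In edgeR the adjusted p of Cdkn1c and Gstm1 was 0.985 and that of Gpx2 and Pfkfb3 0.991. On the lower side, mitotic genes outside the list included Aspm at 13.6 and 2.57 against 0.175, 0.470 and 0.316 CPM, Melk at 4.58 and 0.920 against 0.105, 0.0626 and 0.148, and Pbk at 2.95 and 1.26 against 0.140, 0.0626 and 0.0742.

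The secreted chaperone gene Clu read 271 and 15115 CPM in the controls and 1438, 14538 and 11234 in the deletion libraries. Ptgs2, which encodes cyclooxygenase 2, read 1.75 and 669 against 511, 308 and 3.49 CPM. Like Akr1b7, it was high in control replicate 2 and deletion replicates 1 and 2. In deletion replicate 3 the urothelial genes Upk1a, Upk3b and Krt20 reached 26.1, 15.7 and 22.8 CPM, and at most 0.689 CPM in the other libraries. The uroplakin genes Upk1b and Upk2 were also highest in deletion replicate 3, but the other libraries carried them too. Upk1b read 77.2 and 23.9 CPM in the controls and 45.9, 67.1 and 97.8 in the deletion libraries, and Upk2 2.40 and 0.823 against 0.631, 0.564 and 5.12.

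The mitosis list gave the smallest p by camera with its preset correlation, but not by either other list test. Its unadjusted p was 0.0437 with an estimated correlation and 0.0692 with fry, where the T cell list had 0.0398 and 0.0209. Control replicate 1 was not alone in lying high. The list's median log2 CPM in control replicate 2 lay 0.995 above the highest deletion library, whose group spanned 0.379. That value rests on 1 library and restates that all 22 members lay below both controls, so it adds no separate support. T cells as the dividing cells cannot be told apart from other dividing cells, because the T cell list fell with the mitosis list, and its difference of -0.49 between control replicates 1 and 2, beside 2.14 for mitosis, sets 1 library against 1 in genes near the floor. Different organs in the dissected pieces cannot be told apart from an effect of Ghr deletion, because only 1 control library carried Akr1b7 at 500 CPM or more beside 2 deletion libraries. Those 3 libraries alone gave a median of -1.59, but they were not alike in other organ markers. The seminal vesicle list took 0.847% of counts in control replicate 2 and 24.2% and 26.3% in deletion replicates 1 and 2. Most of that deletion share was Svs2, at 19.2% and 22.8% against 0.331% in control replicate 2. By contrast, 6 of the 9 members were higher in control replicate 2 than in any deletion library. Svs4 took 0.288% of counts there against 0.0713% and 0.145% in deletion replicates 1 and 2, so the summed share does not rank these libraries by tissue content. The real split was 1 of 10 with a median as far from 0 (-2.97 against at most 2.72 in the others), and 3 of the 10 gave at least its 16 lists (8 to 18 in the others, so that the preset test called lists in each grouping); 10 splits are too few for a share under 0.05, and an effect of Ghr deletion stays open beside one of the Cre, which by the labels only the deletion mice carried and which was not tested apart.

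Ghr deletion alone does not account for the high seminal vesicle genes of control replicate 1. Control replicate 2, also without deletion, lay 7.91 below it in the list's median log2 CPM. Control replicate 2 also lay 3.97 above the highest deletion library, and 6 of the 9 members lay below both controls in all deletion libraries. An effect of deletion on part of the pattern therefore cannot be told apart from different tissue content. More seminal vesicle tissue in control replicate 1 than in control replicate 2 may account for the difference between the controls. The 9 members were 51.3 to 458 times higher in control replicate 1. Such tissue in that library alone is argued against for 2 of the 9 members, Svs2 and Svs5, which deletion replicates 1 and 2 also carried, while the other 7 were 12.1 to 458 times higher than in any other library. Whether another gland supplied them there stays open.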
